A study of Homo sapiens with 9 samples.

How the data were processed

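Ribosome profiling sequences the short mRNA fragments that translating ribosomes protect, so the footprint count of a gene reflects both how much of its mRNA is present and how heavily that mRNA is translated. The 9 libraries came from Jurkat clone E6-1, a human T lymphoblast line widely used to study signalling from the T cell receptor. There were 3 biological replicates of each group, per the labels: resting cells, cells activated for 5 h and cells activated for 12 h. Activation used plate-bound anti-CD3 antibody, coated at 10 µg/mL, with soluble anti-CD28 antibody at 5 µg/mL. Together these stimulate the receptor complex and its main costimulatory receptor. The labels' protocol describes library preparation from total RNA with an mRNA sequencing kit. How the footprints were isolated is not given in the sources used here.

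The deposited count table gives whole-number footprint counts for 19569 versioned Ensembl gene IDs in each library, with no normalization. The submitters' processing notes name cutadapt 3.2, Bowtie, bedtools, RSEM and DESeq2 and the genome build GRCh38.p13, without saying which step each served. The annotation release, the treatment of fragments that match several genes, and whether RSEM's estimated counts were rounded are not given in the sources used here. Footprints are short, so genes with near-identical copies could have their counts split or shared by the counting. Among IDs with at least 100 counts in total, 18 pairs had identical counts in every library: 14 were the X and Y listings of the same gene in the annotation, marked PAR_Y, and 4 were pairs of different IDs. A second deposited table gives log2 values made by the authors for 11572 IDs. Checked against the counts, these values equal log2 of the count divided by 1 size factor per library, plus 1, with a largest difference of 5.05e-09. That table lists only IDs with a count in every library and leaves out 1647 of the 13219 such IDs, by a rule that is not stated. Its values are those of the same 9 footprint libraries, and mRNA values were not used here.

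Differences between groups were tested on the counts with edgeR 4.0.16 in R 4.3.3. All 9 libraries entered 1 fit, so that the 3 groups shared an estimate of the spread. Library sizes were scaled with TMM, IDs with too few counts were removed with filterByExpr, which left 13920, and group means were compared with the quasi-likelihood test. P-values were adjusted with the Benjamini-Hochberg method within each comparison, and an ID was called changed at an adjusted p under 0.05. Levels are given as CPM, counts scaled to a common library size with the TMM factors, as mean ± SD over 3 replicates. Rises and falls are therefore relative to the scaled library, and a change in total footprints per cell would not be seen. Fold changes are on the log2 scale with the standard error (SE) of the fit. For an ID with no count in any resting library, the fold is the activated mean over a floor of 3 counts in the resting group. It leaves out the counting error of the activated mean. For an ID with 1 resting count, the ratio of pooled CPM is given with its exact 95% counting interval. The floor and the interval cover counting error only, because amplified fragments are not independent molecules.

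Totals ran from 4343515 counts in 12 h replicate 2 to 18506509 in 5 h replicate 3, and the common biological coefficient of variation of the fit was 15.6%. The procedure was tested on simulated data drawn from the real means and library sizes, with 50 IDs changed by each of 4 fold sizes. The changed IDs were drawn from those with a mean of at least 20 counts. For 5 h versus resting, with 13275 IDs tested, it recovered 46% of the 1.5-fold changes, 74% of the 2-fold changes and 98% of both the 4-fold and 8-fold changes, and 7.06% of its calls were false. For 12 h versus resting, with 13265 IDs, it recovered 56%, 90%, 92% and 100% at the same sizes, with 5.59% false. For 12 h versus 5 h, with 13247 IDs, it recovered 56%, 80%, 98% and 98%, with 4.05% false.

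The 2 comparisons against resting cells share the resting libraries. The overlap of their calls was therefore set beside the number given by independent lists and beside 20 simulations of unchanged groups. In these all 9 libraries, the resting ones included, were drawn anew from the resting means. Both simulated comparisons shared the simulated resting libraries. The p-value cutoffs of the real calls were applied to the simulated tests. Moves back from large 5 h changes were counted in the same way in 20 simulations in which the 12 h libraries were drawn from the 5 h means. The gain of low-abundance IDs was also measured with no low-count filter, with IDs classed by 1 resting library and their gain taken over the other 2, each resting library in turn. To see how many calls arbitrary groupings give, the 6 libraries of each comparison were also split in the other ways possible. The replicate numbers do not pair the libraries across groups by any label, and the fit without a replicate block was the main one.

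The rule for single genes was fixed before the data were examined. It took the 8 IDs with the largest rise and the 8 with the largest fall among called IDs that had a mean of at least 20 counts in the higher group and no overlap between the libraries of the groups. The files pair no ID with a symbol, and 0 of the 59792 genes in the reference gene list carried an Ensembl ID, so 0 of the IDs could be matched to a symbol. The part of the rule that asked for named protein-coding genes could not be applied. The text prints the first 2 IDs that rose and the first 2 that fell at 5 h against resting, and follows them through the other comparisons. For the same reason 38 gene lists and the genes to be reported always, all fixed beforehand, were not tested. The planned tests of genes with sites for 14 miRNA families were not run because 3' UTR sequences were not used here, and the planned test of footprint change beyond mRNA change was not run.

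As a substitute chosen after seeing the data, 3 sets of cell cycle marker IDs were taken from the human marker pairs shipped with scran 1.30.0, which are listed by Ensembl ID. A set held the IDs that appeared in at least 20 pairs as the higher member for a phase, and in at least 90% of their pairs for that phase. Sets were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and Benjamini-Hochberg adjustment ran over the 9 tests. Camera with an estimated correlation and fry were run beside it, and each set's median was set beside those of 10000 lists of other IDs matched on abundance.

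The results were recomputed with DESeq2 1.42.0, upper quartile scaling, no low-count filter, a filter of at least 50 counts in 3 libraries, a fit of only the 6 libraries compared, the replicate number as a block, a test against a 1.5-fold change (glmTreat), scaling without the 50 most abundant IDs, and leaving out each library in turn. Added after seeing the data were the authors' size factors, limma on the authors' log2 table, identical IDs kept once, only IDs averaging at least 4 CPM, and a fit without the library with the fewest detected IDs in each of the resting and 12 h groups.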

Results

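Ribosome footprints were counted in 9 libraries of Jurkat T cells, 3 from resting cells, 3 from cells activated through CD3 and CD28 for 5 h and 3 from cells activated for 12 h. The series title concerns repression of translation and mRNA decay by miRNAs during T cell activation, and these libraries were deposited as its ribosome profiling part. The resting libraries held 9239287, 10171929 and 10160141 counts, the 5 h libraries 9492122, 13026762 and 18506509, and the 12 h libraries 11153533, 4343515 and 7001097. Of 19569 gene IDs, 378 had no count in any library. After thinning every library to 4343515 counts, 15523 ± 332 IDs had a count at rest (SD, n = 3), 16922 ± 364 at 5 h and 16481 ± 379 at 12 h. Every library at 5 h and at 12 h exceeded every resting library, and the two-sided exact permutation p was 0.1 for both comparisons, the smallest that 3 against 3 allows. Log2 CPM correlated across genes at 0.955 to 0.976 within groups and at 0.928 to 0.955 between groups. The first principal component, with 36.3% of the variance, separated all resting from all activated libraries, and the second, with 18.6%, separated 5 h from 12 h.

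The comparison of 5 h with resting cells asks which genes change their footprints early after stimulation. At 5 h the largest rises were of genes with almost no footprints at rest, and many other genes fell by smaller factors. ENSG00000143185.4 rose from 1 count in the 3 resting libraries (0.0388 ± 0.0672 CPM, SD, n = 3) to 359 ± 36.1 CPM. ENSG00000164400.6 rose from no resting count to 54.2 ± 11.4 CPM, 494-fold above the resting floor of 3 counts. Among falling IDs, ENSG00000258947.8 fell from 11.2 ± 2.67 to 0.970 ± 0.912 CPM, and ENSG00000175097.8 fell from 14.7 ± 1.70 to 1.82 ± 1.11 CPM.

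In all, 2230 IDs rose and 2567 fell at 5 h, of 13920 tested. The rises were larger: 894 IDs rose and 373 fell by more than 2-fold, and 362 rose and 37 fell by more than 4-fold. The median log2 fold change was 0.81 among called rises and -0.58 among called falls. Over all tested IDs, 45.7% had no overlap between the libraries of the groups, a pattern that chance gives for 10%. Some rising IDs had few or no counts at rest, and their fitted fold depends on the prior count.

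The ratio for ENSG00000143185.4 at 5 h was 9924, with a 95% counting interval from 1781 to 392000 that reflects its 1 resting count. The fitted log2 fold changes of the falling IDs were -3.40 ± 0.48 (SE) for ENSG00000258947.8, with an adjusted p of 5.42e-06, and -3.01 ± 0.37 for ENSG00000175097.8, with an adjusted p of 8.67e-07, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By the same edgeR test the adjusted p was 1.32e-20 for ENSG00000143185.4 and 3.96e-14 for ENSG00000164400.6. Single libraries set the size of some of these values: the log2 fold change of ENSG00000258947.8 was -4.58 without 5 h replicate 3, that of ENSG00000175097.8 was -3.65 without 5 h replicate 2, and the resting count of ENSG00000143185.4 came from resting replicate 1, without which its fitted value went from 12.85 to 14.88.

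**Figure D1:**
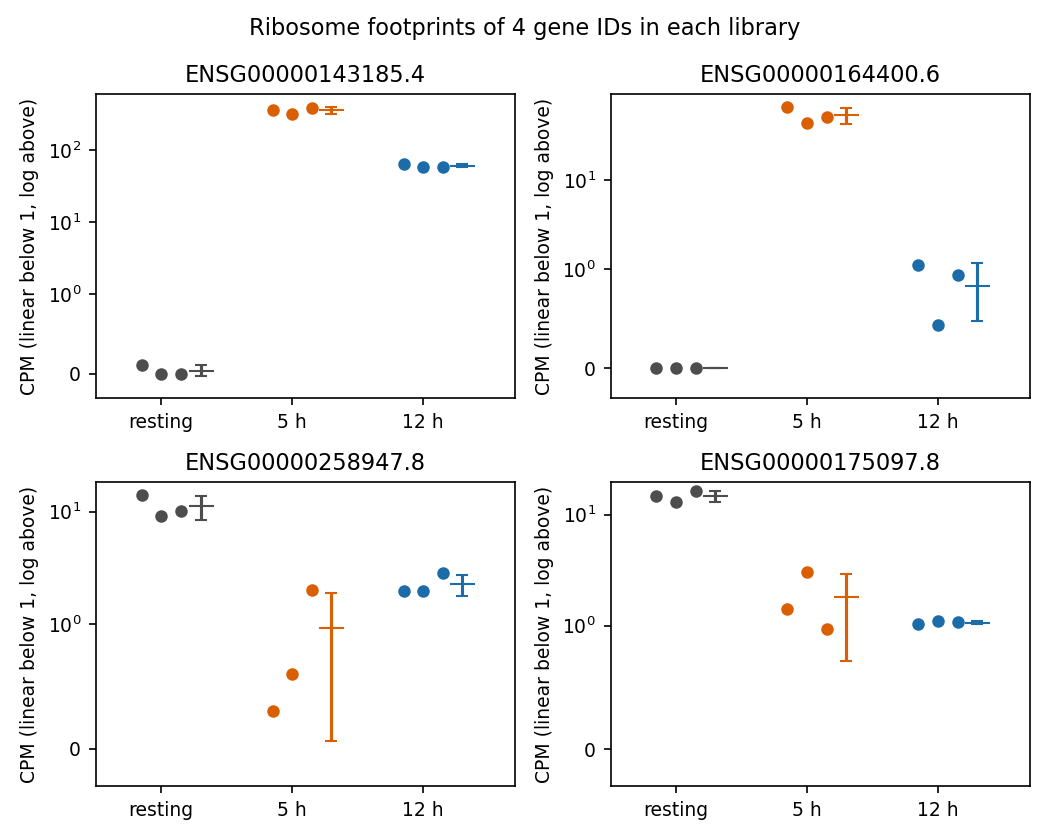
Footprint levels in CPM of the 4 IDs described in the text in resting cells and after 5 h and 12 h of activation, on an axis that is linear below 1 CPM and logarithmic above. Points are libraries and bars the mean ± SD of 3; the 2 IDs in the top row peaked at 5 h, at 359 and 54.2 CPM, and the 2 in the bottom row were lower at both times than at rest.

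The direction of change at 5 h also followed abundance. IDs averaging under 1 CPM had a median log2 fold change of 1.18, and 83.3% of the 552 tested were positive. Such IDs pass the low-count filter more easily when they are high in 1 group, which shapes the size of this value. Of all 6358 IDs that had a count and averaged under 1 CPM, tested or not, 74.1% were higher on average at 5 h than at rest and 65.7% at 12 h. IDs of 1 to 4 CPM had a median of 0.68, those of 4 to 16 CPM 0.10, those of 16 to 64 CPM -0.04, those of 64 to 256 CPM -0.10 and those of 256 CPM or more -0.24. The positive medians of weak IDs were smaller where the IDs and the method both changed. Tested IDs under 4 CPM together had a median of 0.73 at 5 h and 0.56 at 12 h. Limma on the authors' log2 table, which holds 1392 of these 3597 IDs, gave 0.44 and 0.24. The parts due to the IDs, the values and the method were not separated. In the most abundant class, 390 of 726 IDs fell and 115 rose. These directions are relative to the scaled libraries, so a fall here need not be a fall per cell. All IDs averaging under 1 CPM, tested or not, took 0.166% ± 0.0185 of counts at rest, 0.326% ± 0.0765 at 5 h and 0.296% ± 0.0377 at 12 h (SD, n = 3), and every activated library lay above every resting one.

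**Figure D2:**
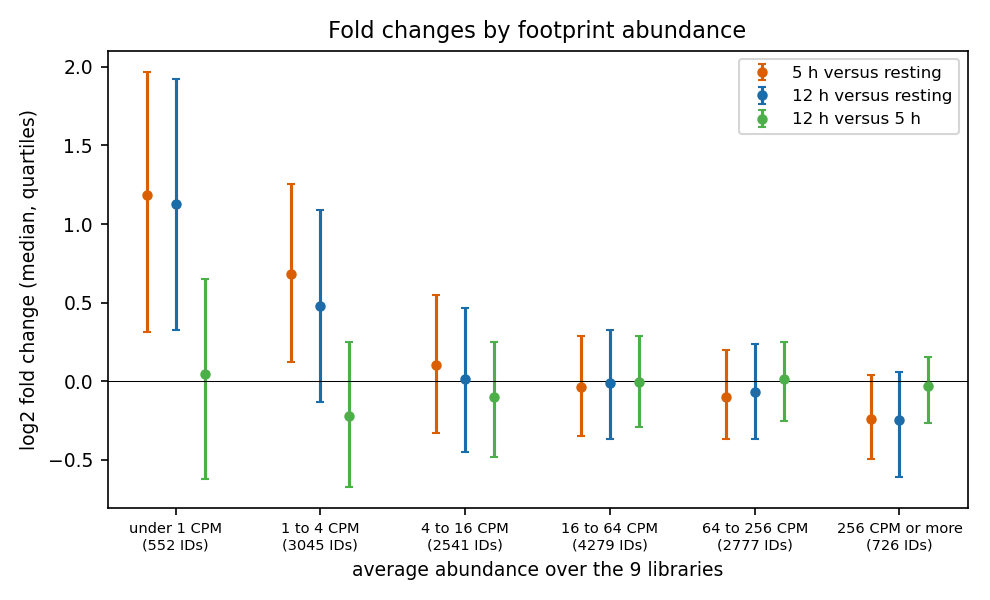
Median log2 fold change of tested IDs grouped by their average abundance over the 9 libraries, with bars from the lower to the upper quartile, for the 3 comparisons. Against resting cells the median fell with abundance, from 1.18 to -0.24 at 5 h and from 1.13 to -0.25 at 12 h; between 12 h and 5 h it stayed between -0.22 and 0.05. The low-count filter favours IDs high in 1 group, which shapes the medians of the weakest classes.

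The comparison of 12 h with resting cells asks which changes are present later. The ID with the largest early rise was still far above rest: ENSG00000143185.4 stood at 60.7 ± 2.94 CPM, a ratio of 1679 with a 95% counting interval from 301 to 66370. ENSG00000164400.6 was at 0.831 ± 0.351 CPM, far below its level at 5 h and 7.57-fold above the resting floor. ENSG00000258947.8 was at 2.25 ± 0.493 CPM and ENSG00000175097.8 at 1.07 ± 0.0349 CPM, both still below their resting levels. By 12 h, 2204 IDs rose and 2683 fell against resting cells.

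More than 2-fold changes were fewer upward and more numerous downward than at 5 h, with 719 IDs higher and 546 lower, and 259 rose and 61 fell by more than 4-fold. The median log2 fold change was 0.76 among called rises and -0.66 among called falls. Over all tested IDs, 45.8% had no overlap between the groups' libraries, against 10% by chance. The balance of directions depended on the filter, since 2549 IDs rose and 2253 fell among IDs with at least 50 counts in 3 libraries, and 2539 rose and 2252 fell among IDs averaging at least 4 CPM. The fitted log2 fold changes at 12 h were -2.30 ± 0.47 (SE) for ENSG00000258947.8 and -3.78 ± 0.42 for ENSG00000175097.8, with adjusted p of 0.000426 and 1.82e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The same edgeR test gave an adjusted p of 2.29e-17 for ENSG00000143185.4 and 9.27e-05 for ENSG00000164400.6. At 12 h ENSG00000164400.6 had only 13, 2 and 7 counts. In the fit of only the 6 libraries compared it did not pass the low-count filter and was not tested. The fitted value of ENSG00000143185.4, 10.29, was 12.31 without resting replicate 1.

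The direct comparison of 12 h with 5 h asks which footprints moved between the time points. Both of the IDs that rose most at 5 h fell again. ENSG00000143185.4 fell by 2.56 ± 0.11 on the log2 scale (SE), from 359 to 60.7 CPM, and ENSG00000164400.6 fell by 5.87 ± 0.29, from 54.2 to 0.831 CPM. The adjusted p-values were 5.21e-14 and 2.09e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and every 12 h library lay below every 5 h library. The IDs that had fallen did not pass this test: ENSG00000258947.8 differed by 1.11 ± 0.50 and ENSG00000175097.8 by -0.76 ± 0.45 (log2, SE), with adjusted p of 0.118 and 0.241 by edgeR.

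Between 5 h and 12 h, 1620 IDs rose and 1877 fell. Large moves were mostly falls: 472 IDs fell and 232 rose by more than 2-fold, and 114 fell and 15 rose by more than 4-fold. The median log2 fold change was 0.59 among rises and -0.66 among falls, and 39.1% of all tested IDs had no overlap between the groups' libraries, against 10% by chance. Which direction held more calls changed with the setting. Without 5 h replicate 3, 1495 IDs rose and 1341 fell, and with at least 50 counts in 3 libraries 1997 rose and 1779 fell. With the authors' size factors 1897 rose and 1678 fell, while upper quartile scaling gave 1749 rises and 1846 falls. Fitting the 6 libraries alone, which also changed the filtered IDs and the scaling, gave 1933 rises and 1853 falls. Without 5 h replicate 3 ENSG00000258947.8 passed the test, at a log2 difference of 2.27 and an adjusted p of 0.00317 by edgeR. The difference for ENSG00000175097.8 was -0.14 without 5 h replicate 2 and -1.07 without 5 h replicate 3, with adjusted p of 0.912 and 0.0882 by edgeR.

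Set side by side, the effects at 5 h and 12 h overlapped widely. Of the 2968 IDs called at both times, 1282 were higher at both, 1517 were lower at both and 169 had opposite directions. Independent lists of these sizes would share 353 rises and 495 falls. In 20 simulations, unchanged groups were compared with shared resting libraries, all drawn anew from the resting means. These shared 33.3 calls on average, and 42 at most, at the p-value cutoffs of the real calls. Deviations of the real resting libraries beyond the fitted spread do not enter the simulations. The simulated lists were short, with 208 and 210 calls on average, and independent lists of that length would share 1.76, so the shared controls raised the overlap of chance calls many-fold. Across genes, which are not independent replicates, the log2 fold changes at 5 h and 12 h correlated at 0.753, against 0.510 in the simulations. Their covariance was 0.649, against 0.0606 simulated, a difference of 0.589. The 3 resting libraries cannot be split into groups of at least 2, so part of the excess may come from the shared controls.

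Large early rises were often partly reversed by 12 h. Of the 362 IDs raised more than 4-fold at 5 h, 235 were still called higher at 12 h, 151 were called lower at 12 h than at 5 h and 6 higher. Of the 37 lowered more than 4-fold, 24 were still called lower and 19 had moved back. Selecting the most extreme values at 5 h favours a move back, since the same 5 h libraries enter both tests. In 20 simulations with no change between 5 h and 12 h, 1.80% of such rises and 5.50% of such falls moved back on average, and 3.21% and 10.9% at most, against 41.7% and 51.4% observed. The simulated sets were larger, with 542.6 rises and 57.65 falls on average against 362 and 37, which can lower the simulated percentages. In counts, 9.8 rises and 3.2 falls moved back on average, and 18 and 6 at most, against 151 and 19. Over all called IDs, the commonest courses were a lasting fall with no called difference between 12 h and 5 h (1043 IDs) and a lasting rise of that kind (908 IDs). An early rise followed by a called fall to a level not called higher than rest was seen for 488 IDs. The mirror image, an early fall followed by a called rise to a level not called lower than rest, was seen for 670. Late changes, not called in the same direction at 5 h and called different between 12 h and 5 h, comprised 521 rises and 713 falls. Direction reversed, with a call on each side of rest, for 76 IDs that were first higher and for 93 that were first lower. The early and late courses were set for each direction by itself and do not leave these reversed IDs out.

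**Figure D3:**
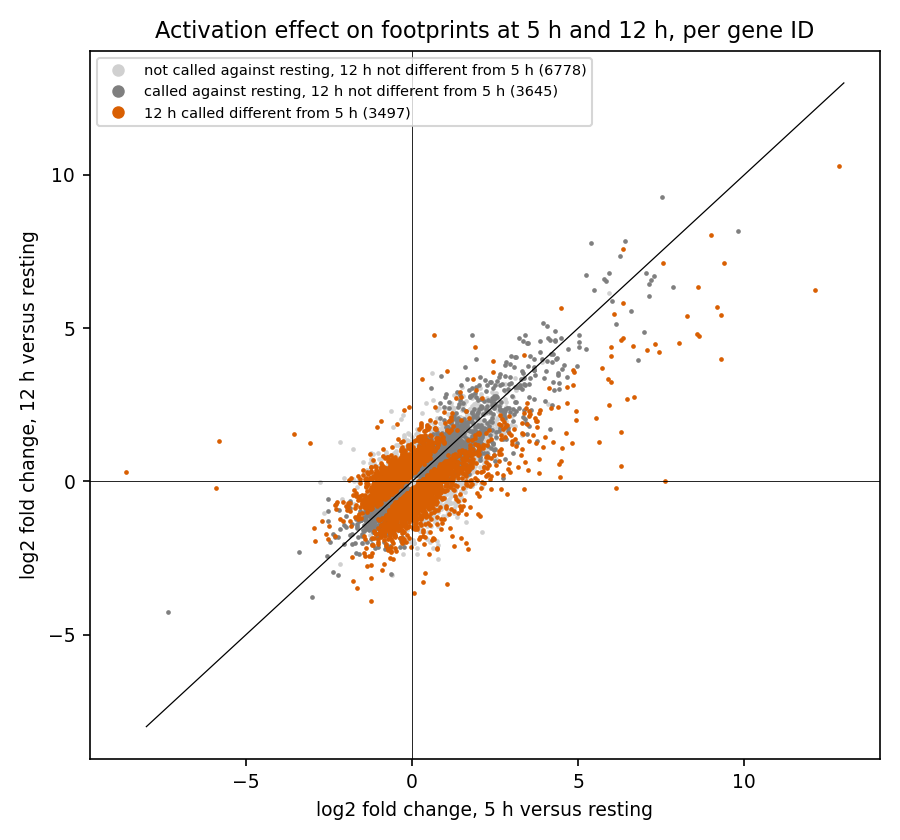
Log2 fold change against resting cells at 12 h plotted against that at 5 h for the 13920 tested IDs, with the line of equal change. Orange points are the 3497 IDs called different between 12 h and 5 h, dark grey points were called against resting at 5 h or 12 h but not between them, and light grey points were not called; the largest early rises lie mostly below the line.

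**Figure D4:**
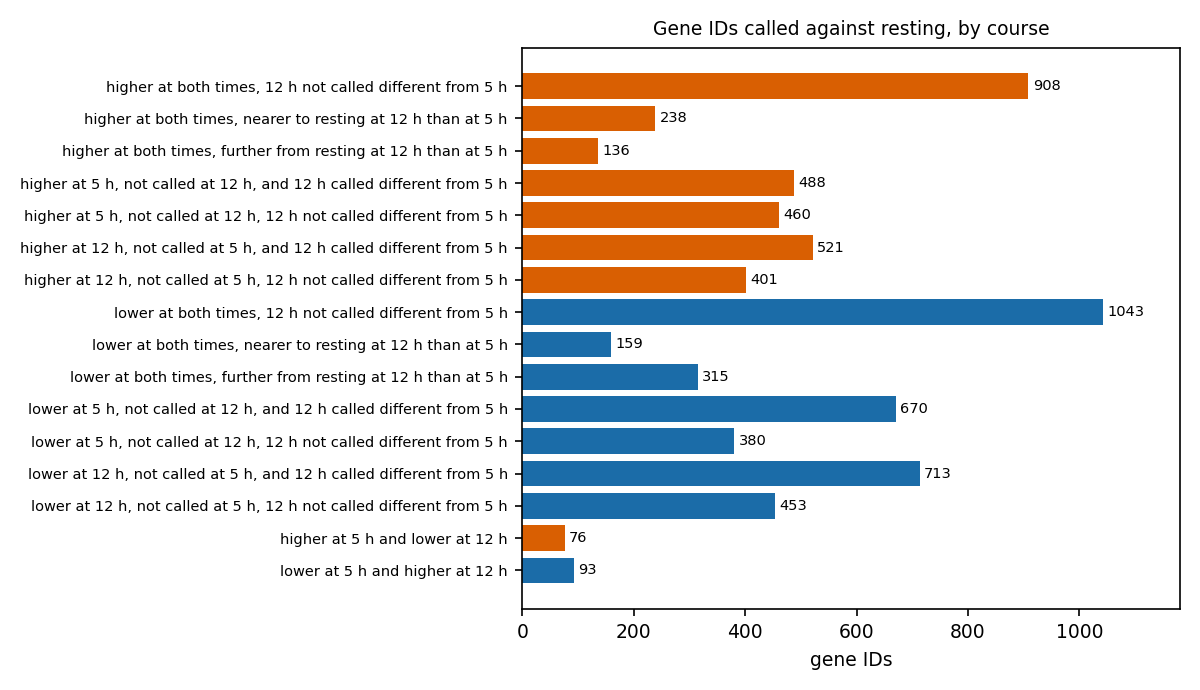
Number of IDs in each course over time, among IDs called against resting at 5 h, 12 h or both. Orange bars count rises and blue bars falls, and the courses that reversed direction take the colour of their first call. Early and late courses were set for each direction by itself. IDs that reversed direction are therefore also counted in those courses, in bars of both colours. The longest bars are lasting falls (1043) and lasting rises (908).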

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

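All tests of explanations in this part were chosen after the results were seen. The activation effect differed between the time points for 3497 IDs, tested directly as 12 h against 5 h. It differed by -2.56 (log2) for ENSG00000143185.4 and by -5.87 for ENSG00000164400.6. Each of the 3 comparisons was refitted for all 10 splits of its 6 libraries into 3 and 3. Only 1 split, the real one, gave as many calls in each case: 4797 against at most 0 elsewhere for 5 h versus resting, 4887 against at most 0 for 12 h versus resting, and 3497 against at most 1 for 12 h versus 5 h. With 10 splits the share cannot fall under 0.1. Every other split mixes libraries of both groups, so a real difference between the groups enters the spread and lowers the calls. The 0 elsewhere therefore does not show how many calls alike libraries would give.

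Low-abundance IDs took a larger share of footprints after activation. A difference in depth is argued against, since activated totals lay on both sides of the resting totals while the lowest activated share was 1.32 times the highest resting share. An even background of extra fragments would give every such ID about the same gain. The gain was measured with no low-count filter. Its median at 5 h for IDs of 1 to 4 CPM was 2.36 times that for IDs with a count under 1 CPM. The ratio ran from 1.95 to 2.68 with the resting library that set the classes. At 12 h the ratio was 1.98, and ran from 1.71 to 2.26. IDs with no count in the resting library that set the classes had a median gain of 0.093 CPM at 5 h and 0.047 at 12 h. Those with a count under 1 CPM gained 0.29 and 0.22, and those of 1 to 4 CPM 0.68 and 0.43. The gain thus rose with the resting level at both times. IDs this near the floor still leave an even background open. The share of IDs under 1 CPM that were higher at 5 h, 74.1%, was not taken at equal depth. Greater average depth at 5 h may add to it. Activation of many weakly translated genes is also open. Such a share would follow from that or from a background that scales with the mRNA, which lie in the same libraries and cannot be told apart. Which of these applies may be seen from the reading frame and length of the fragments, not analysed here.

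A set of 55 abundant IDs, averaging at least 1000 counts and with a count in every library but left out of the authors' log2 table, took 7.12% ± 0.506 of counts at rest, 4.95% ± 0.335 at 5 h and 3.87% ± 0.0401 at 12 h (SD, n = 3). Library scaling alone is argued against, since 1 factor per library moves all IDs alike while the set's median log2 fold change at 5 h, -0.73, differed by -0.47 from that of lists matched on abundance, and the general fall of abundant IDs is too, since at most 0.0001 of 10000 such lists had a median as low, the smallest share these draws can give. Both arguments use the same lists. The draws take the IDs as independent, so the share is too small if the 55 IDs vary together. Reads moving between near-identical copies within the set would keep its summed share, which at 5 h was 0.696 of that at rest; exchange with IDs outside the set was not tested. A smaller share of cells in S phase stays a hypothesis that cannot be told apart from other effects of activation. At 5 h S phase marker IDs gave an adjusted p of 0.266 by limma's camera with an estimated correlation. With the preset correlation camera gave 0.0143, and fry gave 0.00080. As low a median was found in 0.213 of 10000 lists matched on abundance. The result thus depended on the test, and none of these tests links the 55 IDs to S phase. The identity of the 55 IDs may settle which explanation applies.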

How the results depend on the processing

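Some alternatives (the authors' size factors, limma on the authors' log2 table, identical IDs kept once, only IDs averaging at least 4 CPM, and 2 libraries left out) and all those for the cell cycle sets and the abundance medians were chosen after seeing the data. A test against a 1.5-fold change (glmTreat) asks for more than any change and called fewer IDs: 653 higher and 445 lower, 1098 in all, at 5 h versus resting; 527 and 603, 1130 in all, at 12 h versus resting; 217 and 400, 617 in all, at 12 h versus 5 h; and 454 shared in direction by both times. Under it 59.5% of calls at 5 h were higher against 46.5% in the main test, and 35.2% against 46.3% for 12 h versus 5 h. Every other alternative kept these counts within 1.5 times. Leaving out each library in turn gave 4000 to 4744 calls at 5 h, 4021 to 5021 at 12 h, 2831 to 3766 for 12 h versus 5 h, and 2393 to 2591 shared calls, and without both libraries with the fewest detected IDs the counts were 4109, 3744, 2904 and 2188. With the replicate block, the calls numbered 4644, 4689 and 3373, and 2674 were shared; deviations of same-numbered libraries correlated at -0.0625 to 0.0901, and 3 of 9 libraries correlated best with their own number. For the 4 IDs, 255 of 257 alternative values kept direction and side of the threshold. The exceptions were both of ENSG00000258947.8 at 12 h versus 5 h. It passed with limma on the authors' log2 table (1.48) and without 5 h replicate 3 (2.27), the cause not being tested. ENSG00000164400.6 has no value at 12 h versus resting in the fit of only the 6 libraries compared, where it did not pass the low-count filter. With limma on that table, which holds 1392 of the 3597 tested IDs under 4 CPM, their median log2 fold change was 0.44 at 5 h in place of 0.73 and 0.24 at 12 h in place of 0.56. The median of the 55 abundant IDs stayed between -0.79 and -0.68 at 5 h and between -1.30 and -1.19 at 12 h wherever they were tested. In simulation 46% of 1.5-fold changes were recovered at 5 h. That simulation made 170 calls, against 4797 in the real data, so its adjusted threshold was stricter. Recovery of small changes in the real data was therefore not measured. The gene lists, the miRNA site tests and the footprint change beyond mRNA change, with their own alternatives, were not run.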

Other observations

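The cell cycle sets, the tests on them and the description of the abundant IDs below were chosen after seeing the data. Marker IDs of the 3 cell cycle phases had medians below 0 after activation, but none of the sets passed the test against the other IDs by camera with an estimated correlation, and abundant IDs fell in general. At 5 h, 78 of 169 tested G2/M marker IDs fell and 13 rose, with a median log2 fold change of -0.28, 78 of 196 G1 marker IDs fell and 29 rose, with a median of -0.22, and 63 of 192 S phase marker IDs fell and 33 rose, with a median of -0.11. At 12 h the medians were -0.15 for G2/M, -0.25 for G1 and -0.16 for S. Between 5 h and 12 h, 50 G2/M marker IDs rose and 20 fell, with a median of 0.12, while the medians for G1 and S were -0.04 and -0.02, with an adjusted p of 0.940 for each by limma's camera. Lists matched on abundance had medians of -0.05 for G2/M, -0.07 for G1 and -0.08 for S at 5 h. As low a median at 5 h was found in 0.213 of 10000 such lists for S, and in at most 0.0001 for G1 and G2/M; at 12 h these shares were 0.0127 for S, 0.0078 for G2/M and at most 0.0001 for G1. These draws take the IDs as independent, while the estimated correlation was 0.133 for G1, 0.110 for G2/M and 0.0155 for S. Against all other IDs, limma's camera with the preset correlation gave an adjusted p of 4.57e-07 for G2/M, 0.000169 for G1 and 0.0143 for S at 5 h, of 0.00297, 0.000169 and 0.0102 at 12 h, and of 0.00115 for the later rise of G2/M. None of these calls held with an estimated correlation, where limma's camera gave an adjusted p of 0.266 for G2/M and S and 0.365 for G1 at 5 h, 0.367, 0.266 and 0.365 in the order G2/M, S and G1 at 12 h, and 0.365 for the later rise of G2/M. The loss for S, whose correlation was close to the preset 0.01, did not come from correlation among its members alone: with the 3 estimates entered as presets its adjusted p at 5 h was 0.127 by limma's camera, the test with estimation has only the 6 residual degrees of freedom, and the adjustment runs over all 3 sets. Fry in limma, which asks whether the members move 1 way on balance, gave an adjusted p of at most 0.00596 for every set against resting and of 0.0309 for the later rise of G2/M. With the filter of at least 50 counts in 3 libraries the S phase calls were lost, at medians of -0.07 at 5 h and -0.08 at 12 h, the G2/M median at 12 h went from -0.15 to -0.07, with an adjusted p of 0.0455 by limma's camera, and the later rise of G2/M went from 0.12 to 0.20. The marker pairs were trained on another human cell type, and the sets share from 6 to 10 IDs.

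Of the 55 abundant IDs left out of the authors' log2 table, 47 fell and 6 rose at 5 h, 44 fell and 8 rose at 12 h, and 37 fell and 3 rose from 5 h to 12 h. The median log2 fold change was -0.73 at 5 h, -1.27 at 12 h and -0.47 between them, so the fall went on after 5 h. Their summed share was lower in every 5 h library than in every resting library and lower in every 12 h library than in every 5 h library, with a two-sided exact permutation p of 0.1 for each of the 3 comparisons, the smallest that 3 against 3 allows. An analysis that started from the authors' log2 table would not see these IDs. Most of the other 1273 tested IDs left out of that table were not called. Of these 1273, 117 were called higher and 17 lower at 5 h (median 0.76), and 100 higher and 18 lower at 12 h (median 0.62). All tested IDs under 4 CPM had similar medians, 0.73 at 5 h and 0.56 at 12 h. The 1273 IDs were not set beside lists matched on abundance.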
